A study of Homo sapiens with 6 samples.

How the data were processed

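RNA-seq was carried out on 6 libraries of the human endometrial stromal cell line THESC, 3 after a non-targeting siRNA pool and 3 after a pool against SRF. Per the labels' protocols, RNA was purified on columns and treated with DNase, and libraries were made with a stranded mRNA kit, which marks the strand and selects polyadenylated RNA. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.16.1, Subread with featureCounts 2.0.6, DESeq2 1.38.3 and R 4.2.2, without saying what each did. The notes name the builds hg38 and mm10, and the samples are human. The strand setting of the counting is not given in the sources used here, so a gene and its antisense partner may share reads. How reads that fit several genes were treated is not given either, which matters for actins, histones, ribosomal proteins and other families with near-identical copies.

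The authors deposited a table of raw counts for 59251 gene symbols in the 6 libraries, with whole numbers that sum to 53761635 to 76889818 per library. A second deposited table gives a normalized signal for 27185 symbols. Its values equal the raw counts divided by 1 factor per library, and it holds each symbol with a total of 6 counts or more. Those factors, taken as the median ratio over symbols, matched DESeq2's size factors on the same symbols (largest absolute log2 ratio 0 after rounding). The counts were used for all tests, and the normalized table was used only for this check.

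Libraries were grouped by the treatment label. The 59251 symbols were matched to a RefSeq gene table of GRCh38.p14, 57842 by current symbol and 58216 with older symbols, and 36270 had a GENCODE 29 transcript. Genes were filtered with edgeR's filterByExpr, which left 18498 with 99.95% of the counts of each library. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, siSRF against siNT, no covariate) in R 4.3.3. Adjusted p-values are by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 5.23%. Standard errors are the absolute log2 fold change divided by the square root of F, and CPM values are TMM-scaled with the SD over 3 libraries. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of 3.29 to 13.8.

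The tests, the alternatives, the 30 gene lists and the rule for named genes were fixed before the data were examined. The lists came from textbook knowledge, 21 on biology, 5 on markers of cell types and 4 on RNA quality. They hold 873 genes, of which 21 are in more than 1 list. Each list was tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the 30 lists. Camera was also run with the correlation estimated from the data, and fry was run as a second test. Members were counted as risen or fallen over all genes tested and adjusted over the list alone. The rule named SRF, then the 5 largest and 5 smallest log2 fold changes among called genes with a mean log2 CPM of 3 or more, a named symbol and no overlap between the groups. It then took the called members with the largest absolute change and a mean log2 CPM of 1 or more, up to 4 from the SRF/MRTF list, 2 from the SRF/TCF list and from each other list past the threshold, and 1 from each other list.

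The alternatives were DESeq2 size factors in place of TMM, library totals alone, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, counts thinned to the smallest library, and each library left out in turn. Offsets for GC content and transcript length were added after seeing the data. The gene test was checked on simulated counts of the 18498 genes tested, over 8 simulations of siSRF against siNT with 200 genes changed in each. It recovered 38.2% of genes changed 1.2-fold, 61.8% at 1.5-fold, 79.5% at 2-fold and 96.5% at 4-fold, with 8.53% of calls false. In the data 4321 genes were called. The adjusted threshold depends on how many genes change, so these shares need not hold for the data. A simulation with no change, in which 18211 genes passed the filter, gave 1 call. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A comparison of SRF-binding motifs in promoters was left out, since no genome sequence was used here.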

Results

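THESC is a line of human endometrial stromal cells made to divide without limit by the catalytic subunit of telomerase (hTERT). Endometrial stroma is the connective tissue of the uterine lining, which is remodelled in each cycle and in pregnancy. The cells received a pool of small interfering RNAs (siRNAs) against SRF, or a non-targeting pool as control (siNT), with 3 libraries per group. SRF, serum response factor, is a MADS-box transcription factor that acts with MRTF cofactors on actin cytoskeleton genes and with TCF cofactors on immediate early genes. The siRNA was given at 100 nM for 48 hours, and RNA was collected after 3 more days in medium with 2% charcoal-stripped serum. Total gene counts were 70550845, 56266684 and 54184613 in siNT replicates 1 to 3 and 53761635, 76889818 and 75055112 in siSRF replicates 1 to 3. The 10 most abundant genes of a library held 9.48 to 9.92% of its counts, and mitochondrial protein genes held 3.70 to 3.97%. The labels speak of replicates but do not say that these came from separate cultures, so the p-values measure only the spread between these 6 libraries, which may be technical. Only 1 siRNA pool against SRF was used.

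SRF mRNA was lower in every siSRF library than in every siNT library. The deposited SRF counts were 6230, 5042 and 4913 in siNT replicates 1 to 3 and 1802, 2757 and 2568 in siSRF replicates 1 to 3. In CPM, counts scaled to a common library size, SRF stood at 91.1 ± 1.61 (SD, n = 3) in siNT and at 34.0 ± 1.28 (SD, n = 3) in siSRF, so that 37.3% of the control level was left, with single libraries at 36.1 to 38.8%. The log2 fold change was -1.42 ± 0.044 (standard error; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.13e-11). A two-sided exact permutation test of the log2 CPM values gave p = 0.1, the smallest p that 3 against 3 libraries allow. SRF (NCBI Gene 6722) lies on chromosome 6 at 43171269 to 43181506 in GRCh38.p14. The titles of the siSRF libraries also carry the control's name, and the SRF counts go with the treatment label, by which the libraries were grouped here.

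Under siSRF, 4321 of 18498 genes tested changed, of which 2050 were higher and 2271 lower. Among genes changed at least 2-fold, 104 were higher and 237 lower. The 5 deepest falls among named symbols with a mean log2 CPM of 3 or more and no overlap between the groups were in CNN1, ACTA2, TAGLN, LMOD1 and SPOCD1. CNN1, the actin-binding protein calponin 1, fell from 167 ± 4.2 to 17.8 ± 1.14 CPM (SD, n = 3 each). ACTA2, smooth muscle alpha-actin, fell from 1150 ± 29.4 to 135 ± 3.84 CPM, and TAGLN, the actin-binding protein transgelin, from 1731 ± 78.3 to 248 ± 3.25 CPM. LMOD1, the actin nucleator leiomodin 1 of smooth muscle, fell from 206 ± 4.17 to 32.2 ± 0.565 CPM, and SPOCD1 from 72.5 ± 2.49 to 13.3 ± 0.726 CPM. Their log2 fold changes were -3.23 ± 0.051 for CNN1, -3.09 ± 0.042 for ACTA2, -2.80 ± 0.043 for TAGLN, -2.68 ± 0.041 for LMOD1 and -2.44 ± 0.053 for SPOCD1 (standard errors; edgeR adjusted p of 1.21e-13 or below for each). In GRCh38.p14, CNN1 lies on chromosome 19 at 11538851 to 11550323, ACTA2 on chromosome 10 at 88935074 to 88991337, TAGLN on chromosome 11 at 117199294 to 117207465, and LMOD1 on chromosome 1 at 201896456 to 201946548.

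Of the 5 genes with the largest rises among named symbols with a mean log2 CPM of 3 or more and no overlap between the groups, WNT2B, a secreted WNT ligand, went from 4.37 ± 0.440 to 22.2 ± 0.247 CPM (SD, n = 3 each; log2 fold change 2.35 ± 0.074, edgeR adjusted p = 1.13e-11). TGFBI, a secreted matrix protein induced by TGF-beta, rose from 215 ± 13 to 484 ± 20 CPM (log2 fold change 1.17 ± 0.048, edgeR adjusted p = 2.70e-10). SULF2, an extracellular sulfatase of heparan sulfate, rose by 1.39 ± 0.059 on the log2 scale, MEST, an imprinted gene, by 1.30 ± 0.061, and PCDH9, a protocadherin, by 1.13 ± 0.062 (standard errors; edgeR adjusted p of 5.08e-09 or below for each). WNT2B lies on chromosome 1 at 112466541 to 112530165 and TGFBI on chromosome 5 at 136028988 to 136063818. The first principal component, with 42.1% of the variance, separated siNT (-24.6 to -22.7) from siSRF (21.7 to 26.5). The second, with 17% of the variance, spread libraries within groups, with siNT replicates 1 to 3 at 24, -20.8 and -3.75 and siSRF replicates 1 to 3 at -12.4, 12.9 and 0.043. The third, with 15.6%, set siSRF replicate 1 (-24.8) apart from siSRF replicates 2 and 3 (13.1 and 14.3). Scaling by library totals alone raised the share of higher genes among those called from 47.4 to 64.1%, with 3064 higher and 1717 lower. A stricter low-count filter left 46 genes higher and 111 lower at 2-fold or more.

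**Figure D1:**
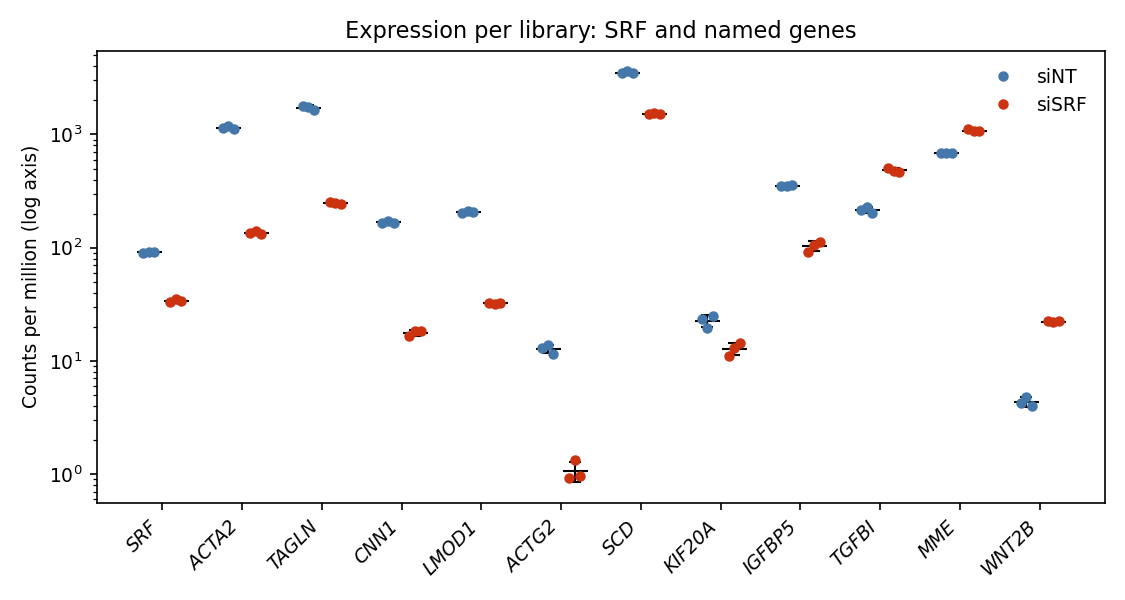
CPM (log axis) of SRF and 11 other genes named in the text in each of the 3 siNT and 3 siSRF libraries; points are libraries, and bars give the mean and SD of a group. For each gene the 3 siSRF values lie outside the range of the 3 siNT values, with ACTA2 at 1150 CPM in siNT and 135 CPM in siSRF. The rule for named genes required this of CNN1, ACTA2, TAGLN, LMOD1, WNT2B and TGFBI, and the groups do not overlap for 37.5% of all genes tested.

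Actin cytoskeleton genes known as SRF/MRTF targets fell as a group. Of 36 members tested, 31 fell, 4 rose and 1 did not pass, with the same counts adjusted over the list alone. The list median log2 fold change was -0.54. Besides CNN1, ACTA2 and TAGLN, ACTG2, the gamma-actin of enteric smooth muscle, fell from 12.8 ± 1.13 to 1.07 ± 0.218 CPM (SD, n = 3 each; log2 fold change -3.56 ± 0.123, edgeR adjusted p = 3.12e-11). ACTG2 counts were 618 to 908 in siNT and 51 to 103 in siSRF libraries, and its near-identical paralog ACTA2 can share reads with it, so its level is less certain. Abundant cytoskeletal members chosen after their values were seen moved less. Beta-actin ACTB had a log2 fold change of -0.65, cytoplasmic gamma-actin ACTG1 of -0.37 and the actin crosslinker FLNA of -1.03. The members that rose were FHL1, FHL2, LIMA1 and TUFT1, at 0.27 to 0.34. FHL1 and FHL2 are LIM-domain proteins, and LIMA1 is an actin-binding LIM protein. In camera, a test of a list against all other genes, the list was lower (adjusted p = 2.99e-18; adjusted p = 0.10 with an estimated correlation).

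Smooth muscle and pericyte markers outside that list fell too. Of 18 tested, 11 fell and 1 rose, also adjusted over the list alone, with a median of -0.52 (camera adjusted p = 1.64e-05; adjusted p = 0.18 with an estimated correlation). MCAM, the adhesion molecule CD146, fell from 85.9 ± 3.52 to 17.7 ± 0.5 CPM (SD, n = 3 each; log2 fold change -2.28 ± 0.049, edgeR adjusted p = 1.21e-13). The member that rose was ABCC9, a subunit of potassium channels, at 0.61, named after its value was seen, and without siSRF replicate 1 there were 2. Focal adhesion and integrin genes were lower, with 18 of 29 down and 4 up (19 and 5 adjusted over the list alone) and a median of -0.26 (camera adjusted p = 1.36e-05; adjusted p = 0.38 with an estimated correlation). The integrin subunits ITGB3, at -1.02 ± 0.054, and ITGA7, at -0.98 ± 0.054, led this list (edgeR adjusted p = 4.03e-09 and 5.75e-09). The number that rose was 2 without siNT replicate 2, siNT replicate 3 or siSRF replicate 2.

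Immediate early genes known as SRF/TCF targets moved both ways. Of 24 tested, 11 fell and 5 rose (12 and 5 adjusted over the list alone), with a median of -0.14. NR4A3, an orphan nuclear receptor, fell from 3.43 ± 0.533 to 0.831 ± 0.0247 CPM (SD, n = 3 each; log2 fold change -2.04 ± 0.162, edgeR adjusted p = 2.98e-07), and the zinc finger factor EGR3 fell by 0.80 ± 0.094 on the log2 scale (edgeR adjusted p = 1.60e-05). The 5 that rose were NR4A2, EGR2, KLF4, JUN and FOSL1, at 0.22 to 0.73. The list was at the threshold (camera adjusted p = 0.0486; adjusted p = 0.38 with an estimated correlation), and it missed it without siNT replicate 3 (adjusted p = 0.068), without siSRF replicate 1 (0.12), with the stricter low-count filter (0.052), with libraries thinned to 1 total (0.056) and with GC and length offsets (0.11).

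SRF cofactors and related MADS-box factors showed 3 of 10 members higher and 2 lower, the same adjusted over the list alone, with a median of -0.067 (camera adjusted p = 0.618). MEF2C, a MADS-box factor, fell by 0.85 ± 0.057 (edgeR adjusted p = 5.60e-08), MEF2D fell by 0.37, and MRTFB, ELK3 and ELK4 rose by 0.25 to 0.32. YAP/TEAD target genes, which respond to cell tension, were split, with 7 of 24 up and 7 down, the same adjusted over the list alone, and a median of -0.037 (camera adjusted p = 0.641). CCN1, a matricellular protein, fell from 839 ± 16 to 504 ± 10.1 CPM (SD, n = 3 each; log2 fold change -0.74 ± 0.037, edgeR adjusted p = 2.42e-09).

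Genes of G2 and mitosis fell almost as a block. Of 36 tested, 31 fell and 0 rose (33 and 0 adjusted over the list alone; 28 to 32 fell when any single library was left out), with a median log2 fold change of -0.54 and a range of -0.83 to -0.11. KIF20A, a kinesin of cytokinesis, fell from 22.8 ± 2.73 to 12.8 ± 1.57 CPM (SD, n = 3 each; log2 fold change -0.83 ± 0.093, edgeR adjusted p = 1.07e-05). BIRC5, the chromosomal passenger protein survivin, fell by 0.75 ± 0.084 (edgeR adjusted p = 1.04e-05). The mitosis list was lower in camera (adjusted p = 6.60e-15; adjusted p = 0.38 with an estimated correlation). Among 37 DNA replication and S phase genes, 6 fell and 3 rose, the same adjusted over the list alone, with a median of 0.042 (camera adjusted p = 0.618). The number that rose was 1 without siNT replicate 2 or siNT replicate 3, and 5 with GC and length offsets. TK1, thymidine kinase 1, fell by 0.57 ± 0.082 (edgeR adjusted p = 1.17e-04). Of 25 p53 targets and cell cycle inhibitors, 9 rose and 8 fell (10 and 8 adjusted over the list alone), with a median of 0.066 (camera adjusted p = 0.637). TP53I3 fell by 0.59 ± 0.045 (edgeR adjusted p = 2.08e-07). In the same libraries 2 of 12 replication-dependent histone genes fell, H2BC21 by 0.84 ± 0.081 and H2BC12 by 0.24 ± 0.050 (edgeR adjusted p = 2.51e-06 and 0.00222), and 0 rose, the same adjusted over the list alone. That list had a median of -0.28 (camera adjusted p = 0.0151; adjusted p = 0.38 with an estimated correlation), and missed the threshold without siSRF replicate 1 (adjusted p = 0.053), with no low-count filter (0.13) and with the stricter filter (0.19).

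Cholesterol synthesis and uptake genes fell, together with fatty acid genes on the same list. Of 30 tested, 24 fell and 0 rose (25 and 0 adjusted over the list alone; 1 rose without siNT replicate 1, and 2 without siSRF replicate 1 or with GC and length offsets), with a median of -0.24 (camera adjusted p = 2.78e-10; adjusted p = 0.10 with an estimated correlation). SCD, the desaturase that makes monounsaturated fatty acids, fell from 3524 ± 81.2 to 1530 ± 8.92 CPM (SD, n = 3 each; log2 fold change -1.20 ± 0.036, edgeR adjusted p = 8.59e-12). Its pseudogene SCDP1, at -1.24, can share reads with it. FASN, fatty acid synthase, fell by 0.55 ± 0.062 (edgeR adjusted p = 1.26e-05). Hypoxia and glycolysis genes were lower as well, with 17 of 33 down and 1 up (17 and 2 adjusted over the list alone; 16 and 5 with library totals alone) and a median of -0.16 (camera adjusted p = 0.00271; adjusted p = 0.18 with an estimated correlation). CA12, a carbonic anhydrase, fell from 149 ± 5.72 to 69.5 ± 1.28 CPM (SD, n = 3 each; log2 fold change -1.10 ± 0.042, edgeR adjusted p = 9.74e-11), and PFKP, the platelet form of phosphofructokinase, fell by 0.73 ± 0.038 (edgeR adjusted p = 3.84e-09). P4HA1, a collagen prolyl hydroxylase, was the member that rose, at 0.34, named after its value was seen, and 2 members rose without siNT replicate 1 or siSRF replicate 3 or with libraries thinned to 1 total, and 4 with GC and length offsets.

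Nuclear genes of oxidative phosphorylation shifted down by a small amount. Of 36 tested, 14 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 1.77e-05; adjusted p = 0.39 with an estimated correlation). NDUFA4, a subunit of the respiratory chain, fell by 0.51 ± 0.045, and UQCRQ, of complex III, by 0.27 ± 0.050 (edgeR adjusted p = 9.81e-07 and 9.12e-04). The number that fell was 8 without siNT replicate 3 or siSRF replicate 2, and 9 without siSRF replicate 3 or with library totals alone. Of 13 mitochondrially encoded protein genes, 3 fell and 0 rose, the same adjusted over the list alone, with a median of -0.073 (camera adjusted p = 0.166). ATP8 was among them, at -0.21 ± 0.054 (edgeR adjusted p = 0.0113), and its adjusted p was above 0.05 without siNT replicate 3 (0.051), siSRF replicate 2 (0.064) or siSRF replicate 3 (0.065). The number of members down was 0 without siNT replicate 3, siSRF replicate 2 or siSRF replicate 3, 1 without siNT replicate 2, 6 without siNT replicate 1 and 7 without siSRF replicate 1. The list passed camera without siNT replicate 1 or without siSRF replicate 1 (adjusted p = 0.027 for both). With library totals alone, 1 member rose and 1 fell.

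Cytosolic ribosomal protein genes were slightly higher in the same libraries. Of 51 tested, 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 3.11e-05; adjusted p = 0.90 with an estimated correlation). RPLP0 rose by 0.25 ± 0.042 and RPL10 by 0.21 ± 0.046 (edgeR adjusted p = 3.85e-04 and 0.00393), and reads of both can be shared with processed pseudogenes. The number that rose was 9 without siNT replicate 1, 8 without siNT replicate 3, 29 with library totals alone and 34 with GC and length offsets, and 1 member fell without siSRF replicate 1. Against the siNT mean, the list median was 0.19 in siSRF replicate 1, 0.044 in replicate 2 and 0.071 in replicate 3, while siNT replicate 2 had 0.045. Genes of endoplasmic reticulum stress and the integrated stress response had 5 of 30 members up and 1 down, the same adjusted over the list alone, with a median of 0.047 (camera adjusted p = 0.166). EIF2AK3, the stress kinase PERK, rose by 0.27 ± 0.059 (edgeR adjusted p = 0.00400). Without siNT replicate 3, 3 members of this list rose and 0 fell, without siSRF replicate 1, 8 rose and 4 fell, without siNT replicate 1, 2 fell, and without siSRF replicate 2, 0 fell. With library totals alone 12 rose and 0 fell and the list passed camera (adjusted p = 0.047), and with GC and length offsets 9 rose and it passed as well (adjusted p = 0.039). Of 34 lysosome and autophagy genes, 10 fell and 3 rose, the same adjusted over the list alone, with a median of -0.045 (camera adjusted p = 0.166). CTSF, the protease cathepsin F, rose by 0.36 ± 0.043 (edgeR adjusted p = 2.24e-05). The number that fell was 6 without siSRF replicate 3, 5 rose with library totals alone, and the list passed camera without siNT replicate 1 (adjusted p = 0.036).

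**Figure D2:**
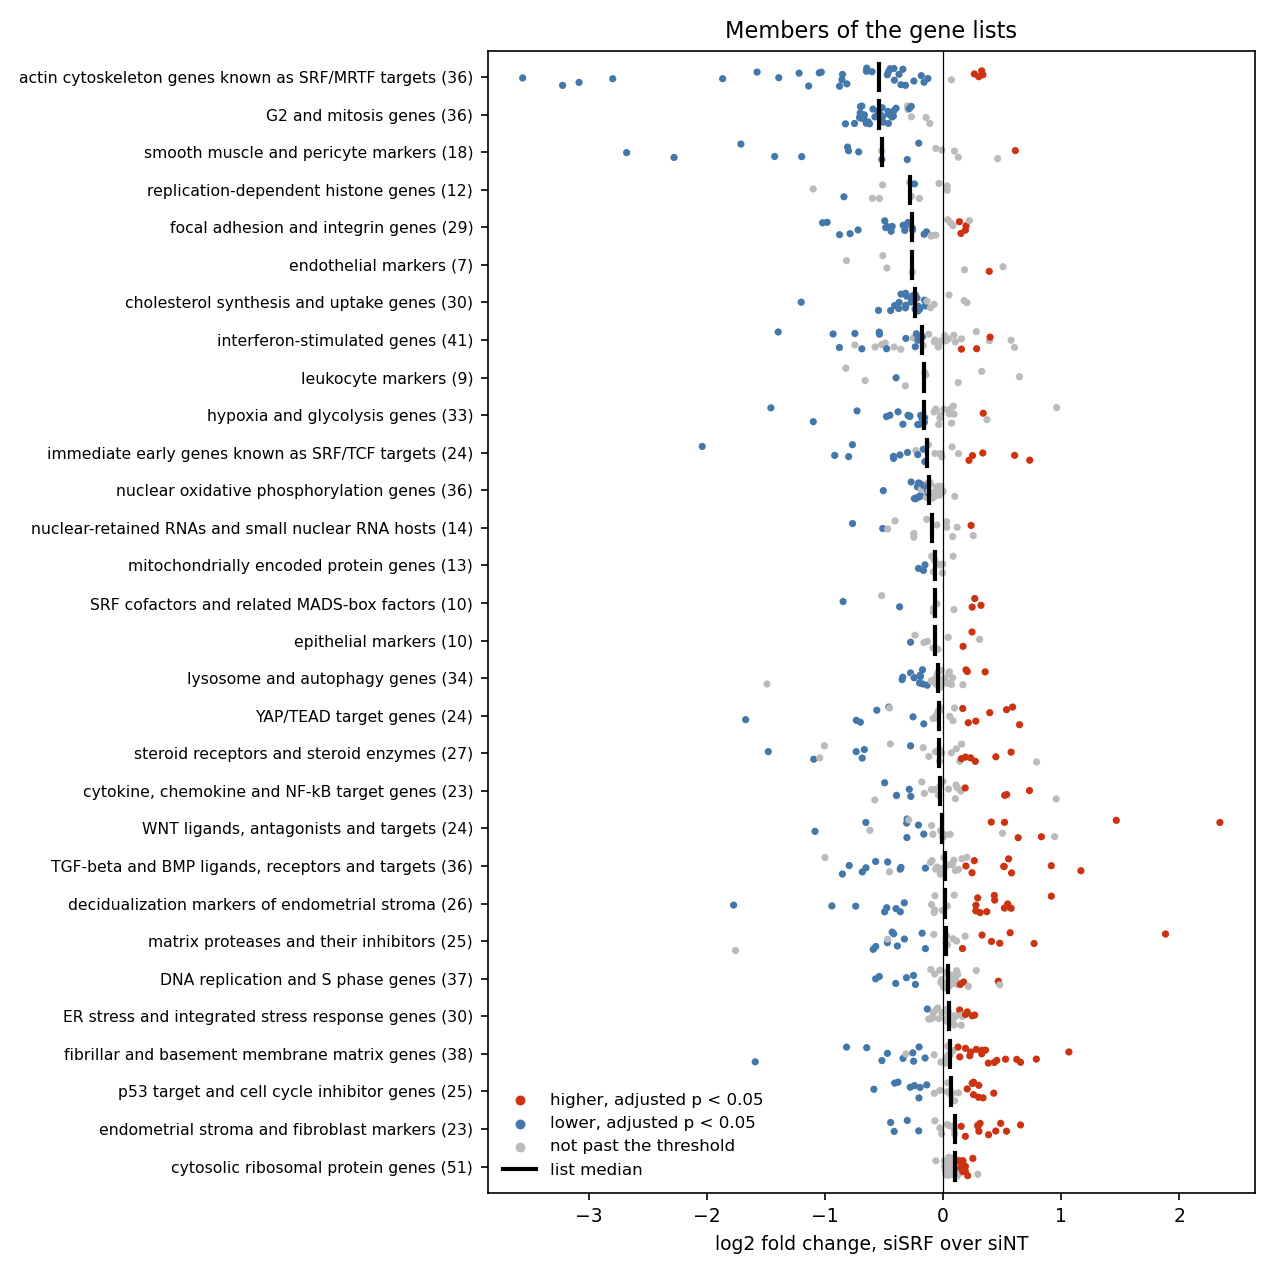
Log2 fold change of siSRF over siNT (x axis) for each tested member of the 30 gene lists (y axis, with the number of members tested); red points were higher and blue points lower at an adjusted p under 0.05, grey points did not pass, and the black bar is the list median. The actin cytoskeleton and mitosis lists both have a median of -0.54, and the cholesterol list has one of -0.24.

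Extracellular matrix genes moved in both directions. Of 38 genes of fibrillar and basement membrane matrix, 17 rose and 10 fell, the same adjusted over the list alone, with a median of 0.055 (camera adjusted p = 0.166, and 0.028 without siSRF replicate 1). TNC, the adhesion-modulating protein tenascin C, fell from 65.0 ± 8.27 to 21.5 ± 0.649 CPM (SD, n = 3 each; log2 fold change -1.59 ± 0.073, edgeR adjusted p = 9.67e-10). Members chosen after their values were seen show the 2 sides. COL14A1 had a log2 fold change of 1.07, the microfibril protein FBN1 of 0.79, the proteoglycan DCN of 0.66 and the fibrillar collagen COL3A1 of 0.53, against -0.82 for THBS1, -0.52 for the basement membrane collagen COL4A1 and -0.47 for fibronectin FN1. Of 25 matrix proteases and inhibitors, 7 rose and 9 fell (7 and 11 adjusted over the list alone), with a median of 0.023 (camera adjusted p = 0.641). MMP10, stromelysin 2, rose from 0.960 ± 0.227 to 3.62 ± 0.773 CPM (SD, n = 3 each; log2 fold change 1.89 ± 0.192, edgeR adjusted p = 4.19e-06).

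**Figure D3:**
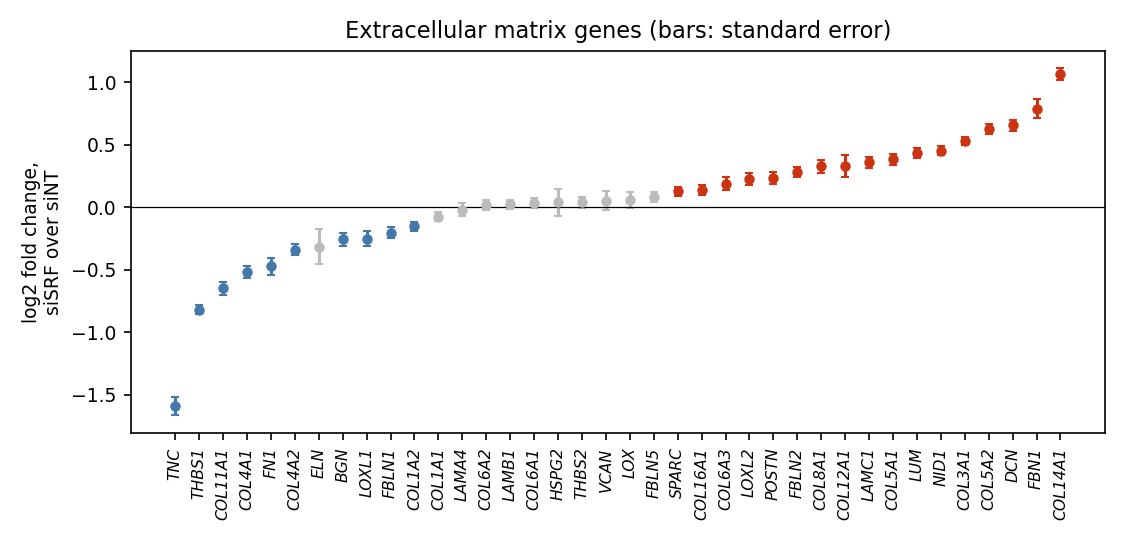
Log2 fold change of siSRF over siNT (y axis) for the 38 extracellular matrix genes tested (x axis, ordered by value), with bars of 1 standard error; red genes were higher and blue genes lower at an adjusted p under 0.05, and grey genes did not pass. TNC lies lowest at -1.59 and COL14A1 highest at 1.07.

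Signalling genes of the TGF-beta and BMP pathways were split, with 9 of 36 up and 9 down (11 and 10 adjusted over the list alone) and a median of 0.014 (camera adjusted p = 0.958). TGFBI belonged to this list. WNT ligands, antagonists and targets had 6 of 24 up and 7 down (6 and 9 adjusted over the list alone), with a median of -0.012 (camera adjusted p = 0.881), and WNT2B stood at the top of this list. In this pathway DKK2, a WNT antagonist, had a log2 fold change of 1.47 and the receptor FZD7 of -1.09, both named after their values were seen.

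Decidualization markers, genes of the change of stroma into the decidua of pregnancy, also went both ways, with 11 of 26 up and 8 down, the same adjusted over the list alone, and a median of 0.016 (camera adjusted p = 0.637). The list held 35 members, and those that did not pass the low-count filter, PRL and IGFBP1 among them, were not tested. IGFBP5, a binding protein of insulin-like growth factors, fell from 354 ± 2.44 to 103 ± 10.4 CPM (SD, n = 3 each; log2 fold change -1.78 ± 0.058, edgeR adjusted p = 1.65e-11). Among members chosen after their values were seen, BMP2 had a log2 fold change of 0.92, the progesterone receptor PGR of 0.58 and FOXO1 of 0.55. On the other side, CRYAB had one of -0.94 and DIO2 one of -0.74. Steroid receptors and steroid enzymes had 6 of 27 up and 6 down (7 and 8 adjusted over the list alone), with a median of -0.032 (camera adjusted p = 0.637). AKR1C1, an aldo-keto reductase that inactivates progesterone, fell by 0.69 ± 0.121 (edgeR adjusted p = 7.03e-04), and its close paralogs AKR1C2 and AKR1C3 can share its reads.

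Markers of endometrial stroma and fibroblasts were higher, with 11 of 23 up and 4 down, the same adjusted over the list alone, and a median of 0.098 (camera adjusted p = 0.0102; adjusted p = 0.18 with an estimated correlation). MME, the peptidase CD10 used to mark endometrial stroma, rose from 686 ± 3.59 to 1081 ± 28.0 CPM (SD, n = 3 each; log2 fold change 0.66 ± 0.037, edgeR adjusted p = 6.62e-09), and NT5E, the ectonucleotidase CD73, by 0.54 ± 0.039 (edgeR adjusted p = 1.30e-07). THY1, S100A4, PDGFRB and FAP were the members that fell, at -0.45 to -0.21. Epithelial markers had 2 of 10 up and 1 down, the same adjusted over the list alone, with a median of -0.065 (camera adjusted p = 0.881). The keratins KRT8 and KRT18 rose by 0.25 and 0.17, and the number that rose was 1 when any of the siNT libraries or siSRF replicate 2 was left out. MUC1, a mucin, was at -0.28 ± 0.094 (edgeR adjusted p = 0.0469), and it missed the threshold in 10 of the alternatives, among them leaving out siNT replicate 3 (adjusted p = 0.24) or any single siSRF library (0.08 to 0.15). Of 7 endothelial markers, the receptor kinase TEK rose by 0.39 ± 0.059 (edgeR adjusted p = 1.74e-04) and 0 fell, the same adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.958). Without siNT replicate 2, 2 of them rose and 1 fell, and with GC and length offsets 2 rose. Their median was the value of ROBO4, at a mean log2 CPM of only -1.2. MMRN2, ESAM, VWF and KDR were also low, at -1.56 to -0.36, so the median rests on genes with few counts. Of 9 leukocyte markers, the lysosomal glycoprotein CD68 fell by 0.40 ± 0.051 (edgeR adjusted p = 3.71e-05) and 0 rose, the same adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.439). Apart from CD68 and CD74, the leukocyte markers had a mean log2 CPM of only -2.47 to -0.55.

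Interferon-stimulated genes had 14 of 41 members down and 3 up (16 and 4 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0907). EPSTI1 fell by 0.93 ± 0.073 (edgeR adjusted p = 2.63e-07). The list passed the threshold without siNT replicate 3 (adjusted p = 4.60e-04) and siSRF replicate 3 (0.044), with library totals alone (0.045), with no low-count filter (0.012) and with the stricter one (0.045). Without siNT replicate 1, 9 members fell, and 5 rose without siSRF replicate 2 and 6 with library totals alone. Cytokine, chemokine and NF-kB target genes had 4 of 23 up and 4 down, the same adjusted over the list alone, with a median of -0.028 (camera adjusted p = 0.958). PTX3, the soluble pattern receptor pentraxin 3, rose by 0.54 ± 0.048 (edgeR adjusted p = 9.46e-07). Without siNT replicate 2 or siSRF replicate 3, 2 members rose, and with library totals alone or GC and length offsets 7 did. Of 14 noncoding RNAs, among them nuclear-retained RNAs and hosts of small nucleolar RNAs, 1 rose and 2 fell, the same adjusted over the list alone, with a median of -0.097 (camera adjusted p = 0.641). NEAT1, the RNA scaffold of paraspeckles, fell by 0.77 ± 0.126 (edgeR adjusted p = 3.63e-04). The number that fell was 1 in each fit without a single library except that without siNT replicate 2, and it ranged from 1 to 3 over the other alternatives. With GC and length offsets 2 members rose.

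Across the 30 lists, 11 passed in camera with its preset correlation and 0 with a correlation estimated from these libraries (5 at an unadjusted p under 0.05), while fry, which asks whether the members of a list move on balance in 1 direction, called 13. These were the lists past camera except the ribosomal genes (fry adjusted p = 0.17), together with SRF cofactors (0.026), endoplasmic reticulum stress genes (0.0029) and matrix proteases (0.027). The median, the mean and camera's direction differed in sign for the lists of matrix proteases, decidualization, cytokines, TGF-beta and BMP, WNT, epithelial and endothelial genes. None of these passed camera.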

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

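The offsets for GC content and transcript length were chosen only after the results were seen. The counts of changed genes, the number of lists past the threshold and the SRF fold change stayed within 1.5 times their value, or on the same side of the threshold, in 95 of 98 comparisons with an alternative. The 3 that moved were the 2-fold counts under the stricter low-count filter and the number of lists past the threshold. The 2-fold counts were 46 higher and 111 lower, with 13631 genes tested. The number of lists was 0 with camera's estimated inter-gene correlation (5 at an unadjusted p under 0.05). A correlation above the preset 0.01 cannot account for each lost call. Its estimate was -0.03 for stromal and fibroblast markers and 0.0045 for hypoxia and glycolysis genes, and both lists had an adjusted p of 0.18 in camera. The other lists past the threshold with the preset had estimates of 0.03 to 0.67. What removed the calls was not tested. Leaving out 1 library gave 1430 to 2173 genes higher and 1690 to 2320 lower. DESeq2's own test gave 1899 higher and 2122 lower, 71 and 176 of them at 2-fold or more, against 104 and 237 with edgeR. With GC and length offsets 2565 were higher and 2439 lower, and 5 genes called without them had the opposite sign. Over the lists, 477 results were the same, 19 fell below the threshold (11 of them with the estimated correlation) and 11 rose above it. Over the named genes 739 were the same and 13 lost their call, 10 for MUC1 and 3 for ATP8, and no named gene reversed. A list that passed in neither fit was counted as the same even where its direction changed. List medians near 0 could change sign, as for YAP/TEAD targets, from -0.037 to 0.011 with library totals alone. The labels state no pairing by replicate number. Deviations of same-numbered libraries from their group means correlated at -0.019, -0.057 and 0.048. These values show no sign of a pairing, but with 3 libraries per group they cannot exclude one. With the replicate number as a block 1904 genes were higher and 2171 lower, 94 and 223 of them at 2-fold or more, and 11 lists passed. The planned comparison of SRF-binding motifs in promoters, and its alternatives, were not run. Thinning each library to the smallest total left 2016 genes higher and 2230 lower. At the deposited depth and 3 libraries per group, 38.2% of simulated 1.2-fold changes were recovered. Those simulations changed 200 genes, against 4321 called in the data, so this share need not hold for the data.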

Other observations

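The test of fewer G2 and mitotic cells, that of a single library, that of library depth and that of shared actin reads were chosen only after the results were seen, as were the genes of the next paragraph and the comparison of gene families.

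Genes outside the 30 lists changed as strongly as many within them. Those named here were taken from the 6 smallest p in each direction among genes in no list, with a mean log2 CPM of 3 or more, a named symbol and no overlap between the groups, leaving out SRF, SPOCD1, SULF2 and MEST, which the report names. IRAG1, a substrate of cGMP-dependent protein kinase that restrains calcium release, fell from 171 ± 3.89 to 37.1 ± 0.806 CPM (SD, n = 3 each; log2 fold change -2.21 ± 0.042, edgeR adjusted p = 2.49e-14). JPH2, junctophilin 2, which ties the plasma membrane to the sarcoplasmic reticulum in muscle, fell from 31.7 ± 0.210 to 9.86 ± 0.174 CPM (edgeR adjusted p = 1.13e-11). CEMIP, which takes part in hyaluronan breakdown, had a log2 fold change of -1.92 ± 0.059, and the sorting receptor SORT1 one of -1.38 ± 0.043. On the other side, SIPA1L2 went from 34.6 ± 1.40 to 75.2 ± 0.691 CPM and OGFRL1 from 63.7 ± 2.92 to 131 ± 5.74 CPM (edgeR adjusted p = 1.61e-10 and 8.37e-10), and NCKAP5 and ERMP1 rose by 1.01 ± 0.045 and 1.02 ± 0.049.

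Families of genes that share a symbol root were compared with all 13389 coding genes tested. Of 233 families, 0 were enriched among higher or lower genes by Fisher's exact test after adjustment over 466 tests (32 tests had an unadjusted p under 0.05), and the lowest adjusted p was 0.057, shared by the ATP, NDUFB and PSMD roots (7 of 11 NDUFB and 8 of 14 PSMD genes were lower). Among 31 families with at least 10 called genes, the direction of the calls stood out for the ZNF root of zinc finger genes, with 80 higher and 10 lower of 471 tested. Thus 88.9% of its called genes were higher, against 47.1% of the 3839 other called coding genes (Fisher's exact test, p = 2.2e-16, adjusted p = 6.7e-15). This test counts genes as independent although all were measured in the same 6 libraries, so its p does not measure the spread between libraries. The shifts were small, with a median of 0.093 over the family.

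The zinc finger shift may have a technical source, and GC content with transcript length and library depth were weighed. ZNF transcripts had a median GC content of 43.3% and a length of 3816 bases, against 48.5% and 3045 over the tested genes, yet with offsets for both the excess of higher over lower ZNF calls was 72, against 70 without them, which argues against such a bias as the whole cause. For depth, the family median against the siNT mean was 0.038, -0.021 and -0.013 in siNT replicates 1 to 3 and 0.12, 0.098 and 0.075 in siSRF replicates 1 to 3, and a linear model with the log2 total count as a term put the difference between groups at 0.093 (95% interval 0.0055 to 0.18, 3 residual degrees of freedom), too wide to settle how much of it goes with depth, although siSRF replicate 1 had the smallest total, and thinning to 1 total, which keeps each library's proportions, left 81 ZNF genes higher and 15 lower with a median of 0.093. Over the fits without a single library the median fold change of the family stayed at 0.082 to 0.10, while the excess of calls was 75, 30 and 31 without siNT replicates 1 to 3 and 53, 45 and 35 without siSRF replicates 1 to 3, and with library totals alone they were 0.14 and 120. That lower SRF itself raises these genes stays open as a hypothesis, with no test of its own here.

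The mitosis genes fell while the replication genes had a median near 0. With any single library left out, the mitosis median was at most -0.50, and with GC and length offsets it was -0.54, which argues against a single library or such a bias as the cause. The mitosis median minus the replication median was 0.032, -0.091 and 0.034 in siNT replicates 1 to 3 and -0.69, -0.62 and -0.50 in siSRF replicates 1 to 3, a mean difference between groups of -0.60. Whether S phase also shifted stays open, since 6 replication genes fell and 3 rose. The median of the replication-dependent histone genes was -0.32, -0.33 and -0.17 in siSRF replicates 1 to 3, below the lowest siNT value of -0.047. That list, 1 of RNA quality, says little on S phase. Its mRNAs lack a poly(A) tail, while the libraries were selected for polyadenylated RNA. Of its members 10 of 12 did not pass, and several had few counts, with H3C10 and H3C4 at a mean log2 CPM of -2.14 and -2.22. With the stricter low-count filter its median log2 fold change was -0.14 (camera adjusted p = 0.19). Fewer cells in G2 and mitosis, and a lower transcript level per dividing cell, may each account for the fall and were not told apart, as no cell cycle measurement was used here.

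ACTG2 could fall because reads of its paralog ACTA2 were counted as ACTG2. In that case both would fall alike. ACTG2 counts per 1000 ACTA2 counts were 11.3, 11.7 and 10.3 in siNT replicates 1 to 3 and 6.94, 9.46 and 7.23 in siSRF replicates 1 to 3, and the log2 fold changes differed by -0.48 ± 0.13 (standard error), which argues against shared reads as the whole source of the ACTG2 counts. A part of them may still come from ACTA2.

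The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 4321 changed genes and the highest other split 1. For genes changed at least 2-fold the values were 341 and 1, again with 1 of the 10 splits as large as the real one, and for gene lists past the threshold 11 and 8, also with 1 of 10. Each other split sets 2 libraries of a group with 1 of the other, so it keeps part of the difference between groups and adds the variation between libraries of a group. The SRF/MRTF and mitosis lists each passed in 7 of the 9 other splits, the ribosomal list in 6, the cholesterol list in 5 and the oxidative phosphorylation list in 4. For some lists another split gave a lower camera adjusted p than the real one, among them 1.9e-13 against 3.11e-05 for ribosomal genes, 1.3e-11 against 0.0907 for interferon-stimulated genes, 1.4e-05 against 0.166 for mitochondrially encoded genes, 9.8e-16 against 6.60e-15 for mitosis genes and 0.0033 against 0.0151 for histone genes. Lysosome and autophagy genes (0.0074 against 0.166), replication genes (0.036 against 0.618), fibrillar and basement membrane matrix genes (0.036 against 0.166) and the list with nuclear-retained RNAs (0.044 against 0.641) also passed in another split but not in the real one. The lists named here with a lower adjusted p in another split thus also vary between libraries of the same group. The splits do not show this for the SRF/MRTF and cholesterol lists. Against the siNT mean, the SRF/MRTF median was -0.018, 0.013 and 0.013 in siNT replicates 1 to 3 and -0.53 in each siSRF library. The cholesterol median was -0.025, 0.025 and -0.0083 in siNT replicates 1 to 3 and -0.27, -0.24 and -0.25 in siSRF replicates 1 to 3.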
